A study of Homo sapiens with 10 samples.

How the data were processed

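RNA of CD34+ bone marrow cells of 5 patients with multiple myeloma was measured before and after lenalidomide consolidation on a 3′ expression array with biotin-labelled targets, per the labels. The total RNA was purified with a column kit for small samples, per the labels' protocols. The authors deposited 1 value per probe set and sample, made with RMA (robust multi-array average) per the submitters' processing notes, which give no version. RMA corrects the background, applies quantile normalization and summarises the probes of a probe set on the log2 scale. The deposited log2 values had a further property seen in the file itself: the median over the 10 samples was 0 for each of the 22277 probe sets, so the values were centred per probe set after RMA. The step that did this is not given in the sources used here, and neither is the base of the logarithm, which was taken as 2. The centring keeps differences between samples and removes the level of each probe set. It follows that signal over background was unknown, that no gene could be called absent or near background, and that a difference of a gene close to background could be compressed. Background, scale and centring could not be checked against scanner values, which were not used here.

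Samples were grouped by the time point that the labels give, 5 before and 5 after, and paired by the patient that the labels name. The columns left unmatched to a sample numbered 0. Deviations from the group means of the 2 samples of a patient correlated at 0.145 on average over genes, from 0.038 to 0.376, and those of samples of different patients at -0.037. Across columns of centred values the lowest correlation was -0.40, which centring by itself favours. The sample medians lay between -0.020 and 0.030. With 5 pairs the number of arrays limits the precision, and the p-values of single genes measure the spread between patients.

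Probe sets were named from the platform's annotation, and the gene identifiers were looked up in the human reference annotation, in which 11954 of 11964 identifiers were found. Of the probe sets, 62 were array controls, 19064 had 1 gene, 1043 several and 2108 none. Genes of the Y chromosome and of X inactivation were left out of the tests of genes and lists, and 19033 probe sets with 1 gene were used. Other genes that can tell something of a person, such as HLA genes, stayed in the tests and are not named. Values of probe sets of the same gene were averaged, which gave 11939 genes, 4304 of them with several probe sets. The plan made before the data were examined was to leave out the dimmest 25% of the probe sets and to use the probe set with the highest mean per gene. Neither can be done with values that hold no level, so no filter was applied and the mean of a gene's probe sets was used, both of which had been listed as second choices.

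Differences were tested with limma 3.58.1 in R 4.3.3, with the patient as a block, empirical Bayes moderation and two-sided p-values adjusted by Benjamini and Hochberg over 11939 genes at a threshold of 0.05. A count of genes with an unadjusted p under 0.05 and at least a 1.5-fold difference was added as a description. Gene lists for progenitor lineages, other marrow cells, pathways tied to the drug and signs of sample handling, 33 in all, were fixed before the data were examined. Each list had at least 5 measured genes and was tested against all other genes with limma's camera at a preset correlation of 0.01 between genes, and also with an estimated correlation and with fry, whose main p tests a shift to 1 side and whose mixed p tests change in either direction. Camera takes genes as its units, so its p-values at the preset correlation do not measure the spread between patients. The mean difference over a list's genes was taken per patient, with mean and SD over 5 patients and an exact sign-flip permutation test over 32 assignments. Fold differences are 2 to the power of the log2 difference. Marker lists of marrow macrophages, core T cells and cytotoxic effector cells were written after the shifts of the fixed lists had been seen and before they were tested. Values after ± are SEs of limma's fit for genes and SDs over patients for lists.

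Genes were named by a rule fixed before the data were examined. It took up to 12 genes per direction with the same sign in 5 of 5 patients and the largest mean difference, filled with genes at an unadjusted p under 0.05 where fewer passed the adjustment. It added up to 4 genes with the smallest p in the direction of each called list, and 10 genes named in advance, CRBN, IKZF1, IKZF3, CSNK1A1, MYC, IRF4, GATA1, CEBPA, SPI1 and CD34. The rule gave 105 genes. Genes named as the ones that passed over a list alone, or chosen after their values were seen, come in addition. Genes of the MHC class II molecules were tested within their list and not named.

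The test was tried on simulated data with the design and the residual spread of the real genes and 200 genes changed by known amounts. Of 50 genes per size, 32% (16) were recovered at a log2 difference of 0.5, 82% (41) at 1, 98% (49) at 1.5 and 100% (50) at 2. Beside these calls stood 18 false calls among 11712 unchanged genes. The adjustment is easier to pass where many genes change. These shares therefore do not carry over to the real data, where AIM2 at -2.36 did not pass. In the simulation a list shifted by 0.3 was called, and 0 of 28 lists that share no gene with it were. The noise was drawn for each gene on its own, so the simulated lists held no correlation between genes. In the real data the estimated correlation reached 0.72 in the type I interferon list. The 0 of 28 therefore says nothing of false calls of lists in the real data. The alternatives covered the pairing, a random patient effect, repeated quantile normalization, centring of samples, array quality weights, the variance model, a plain paired test, the order of the sample numbers in the labels (taken as an order of handling, which no label states), each pair left out in turn, the choice of probe sets, the filter and the gene set test. Tables and figures used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.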

Results

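Gene expression was measured with a 3′ expression array in CD34+ haematopoietic stem and progenitor cells, the bone marrow cells that give rise to the blood lineages. The cells came from 5 patients with multiple myeloma, a cancer of plasma cells. Each patient gave 1 sample before lenalidomide consolidation, at cycle 0, and 1 sample after it, at cycle 6, which made 2 groups of 5 samples in 5 pairs. No untreated patients were among the samples, so effects of the drug cannot be told apart from those of the time between samples. Lenalidomide is an immunomodulatory drug that binds cereblon, encoded by CRBN, and thereby directs a ubiquitin ligase to transcription factors such as IKZF1 and IKZF3. The deposited values were differences from each probe set's median over the 10 samples, on a log scale whose base was taken as 2 because none was stated. They gave differences between samples and no level of expression, so signal over background was unknown. Values for 11939 genes were compared, and the median value of a sample lay between -0.020 and 0.030. The number of arrays limited the precision.

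The before and after groups accounted for 21.3% of the variance over all genes, against 11.1% expected from their degrees of freedom alone. Patient accounted for 45.0%, against 44.4% expected in the same way. Neither share was tested. The leading principal component carried 25.6% of the variance between samples, and the before and after groups accounted for 71.2% and the patients for 12.1% of the spread of the sample scores on it. The next component carried 16.4%, of whose spread the patients accounted for 71.0% and the before and after groups for 10.1%.

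The comparison of samples after with samples before lenalidomide asked which genes differed in the progenitors of the same patient. HMOX1, which encodes haem oxygenase 1, the enzyme that degrades haem, fell by 1.71 ± 0.14 on the log2 scale (SE, n = 5 pairs), a 3.26-fold lower value. HMOX1 was lower after therapy in 5 of 5 patients, and limma's paired fit gave an adjusted p of 0.0224. It was the 1 gene of 11939 that passed the adjustment, with 0 genes higher and 1 lower. Marker genes of marrow macrophages moved with HMOX1, with a mean shift of -0.67 ± 0.46 over 17 genes (SD, n = 5 pairs) and lower values in 5 of 5 patients. Of these markers, 3 were already seen among the named genes, MSR1, CD5L and CD163. The other 14 had a mean shift of -0.50 ± 0.46, also lower in 5 of 5 patients. Leaving out each of 3 of the 5 pairs in turn ended the call of HMOX1, with log2 differences of -1.63, -1.80 and -1.67, and the fit without the pairing and a plain paired test ended it too, both at -1.71. The fit without the pairing passed 4 other genes, UBE2C, MSR1, GZMB and SMPDL3A, the last of which was chosen after its values were seen.

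Many genes differed by smaller margins that did not pass the adjustment. At an unadjusted p under 0.05, limma gave 1120 genes higher and 731 lower, against 597 in all by chance. A difference of at least 1.5-fold at that p was found for 421 genes, 195 higher and 226 lower. The other ways of swapping before and after within the pairs gave at most 384 such genes and a median of 49. The difference had the same sign in 5 of 5 patients for 1052 genes in the higher and 628 in the lower direction, or 14.1% of the genes against 6.25% by chance for independent genes. The other ways of swapping before and after within the pairs gave at most 1340 genes with the same sign in all patients, against the real 1680, and a median of 550. The median difference over all genes was 0.003. Leaving out 1 of the pairs gave 217 genes higher and 365 lower at 1.5-fold, and leaving out another gave 208 and 278. Leaving out each of the others turned the balance, to 220 higher and 169 lower, 179 and 167, and 195 and 166. A plain paired test turned it as well, with 137 higher and 94 lower. Leaving out 1 of the pairs brought 102 genes past the adjustment, and leaving out each of the others gave 0, 0, 0 and 3.

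Red cell genes stood among the 12 genes with the largest positive differences that had 1 direction in 5 of 5 patients, none of which passed the adjustment over all genes. AGAP1, an Arf GTPase-activating protein, differed by 1.93 ± 0.28 (SE, n = 5 pairs, adjusted p = 0.0876). GZMB, the granule protease granzyme B, differed by 1.93 ± 0.26. A list of 10 other genes of cytotoxic effector cells, which leaves out GZMB, had a mean shift of -0.65 ± 0.37 (SD). Of these 10 genes 9 lay lower, while CST7 stood at 0.38. CDH1, the adhesion molecule E-cadherin, differed by 1.79 ± 0.22. The red cell membrane genes XK and RHAG differed by 1.91 ± 0.25 and 1.74 ± 0.25, and the beta-globin gene HBB by 1.48 ± 0.30. EPX, the eosinophil peroxidase, differed by 1.87 ± 0.34 and LTBP1, a binding protein of latent TGF-beta, by 1.51 ± 0.24. FAM171A1, the tubulin gene TUBAL3, the mechanosensitive channel PIEZO2 and the copper transporter ATP7B differed by 1.62, 1.53, 1.52 and 1.47. The adjusted p of these 12 genes lay between 0.0777 for XK and CDH1 and 0.133 for TUBAL3 and HBB.

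Besides HMOX1, genes known from macrophages and interferon-induced genes stood among the 12 genes with the largest negative differences of 1 direction in 5 of 5 patients. AIM2, a sensor of cytosolic DNA, differed by -2.36 ± 0.37 (SE, n = 5 pairs, adjusted p = 0.0908). GIMAP4, a GTPase of lymphocytes, differed by -2.30 ± 0.53, and PLA2G7, the platelet-activating factor acetylhydrolase, by -1.84 ± 0.36. The scavenger receptor gene MSR1 and CD5L, both known from macrophages, differed by -1.71 ± 0.25 and -1.35 ± 0.23. TNFRSF1B, a receptor of tumour necrosis factor, differed by -1.56, the chemokine gene CCL5 by -1.48 and PID1 by -1.40. The interferon-induced genes OAS1 and IFIT1 differed by -1.37 each, with SEs of 0.43 and 0.46, and IFIT1 by -0.75 without 1 of the pairs. CRHBP, which is enriched in haematopoietic stem cells, differed by -1.36 ± 0.22. The adjusted p of the 11 genes other than HMOX1 lay between 0.0876 for MSR1 and 0.232 for IFIT1.

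**Figure D1:**
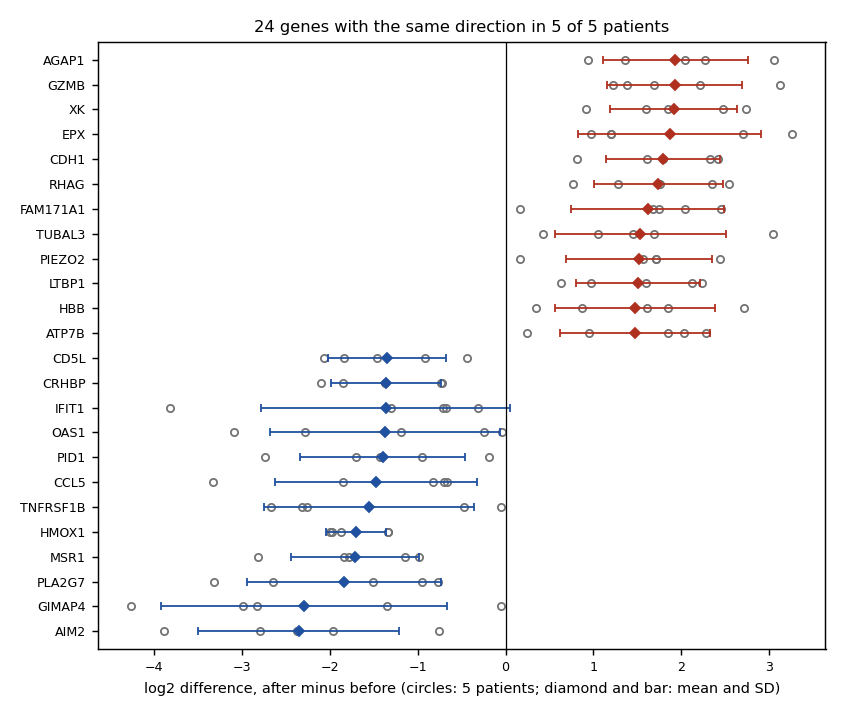
The log2 difference, after minus before lenalidomide, of 24 genes with 1 direction in 5 of 5 patients, with genes on the vertical axis. Circles are the 5 patients, and the diamond and bar give mean and SD; HMOX1 has the narrowest bar of the genes below 0, at -1.71 with an SD of 0.34.

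The gene lists asked whether lineages and pathways moved as sets within the progenitors. Genes of cell division, of the red cell lineage, of megakaryocytes and of oxidative phosphorylation lay higher after therapy, while interferon, immediate early, MHC class II, stem cell, T cell and B cell genes lay lower. With limma's camera at the preset correlation of 0.01, 20 of the 33 lists differed from the other genes, 10 higher and 10 lower. With an estimated correlation between the genes of a list, 0 of the 33 lists passed, with a smallest adjusted p of 0.314, and 3 had an unadjusted p under 0.05. Fry, which tests each list on its own, passed 1 list, DNA replication and G1/S, in its test of a shift to 1 side, and 18 lists in its test of change in either direction. The other ways of swapping before and after within the pairs called a median of 12 lists and at most 21 with the preset correlation. The mean shift had the same sign in 5 of 5 patients for 11 lists, and the other swaps gave at most 6. In an exact sign-flip permutation test over the pairs, two-sided, these 11 had p = 0.0625, the smallest that 32 assignments of 5 pairs allow, and 0.188 after adjustment. Of the 11, the stem cell, adhesion and MHC class II lists each had 1 pair close to 0, at -0.006, -0.014 and -0.010.

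**Figure D2:**
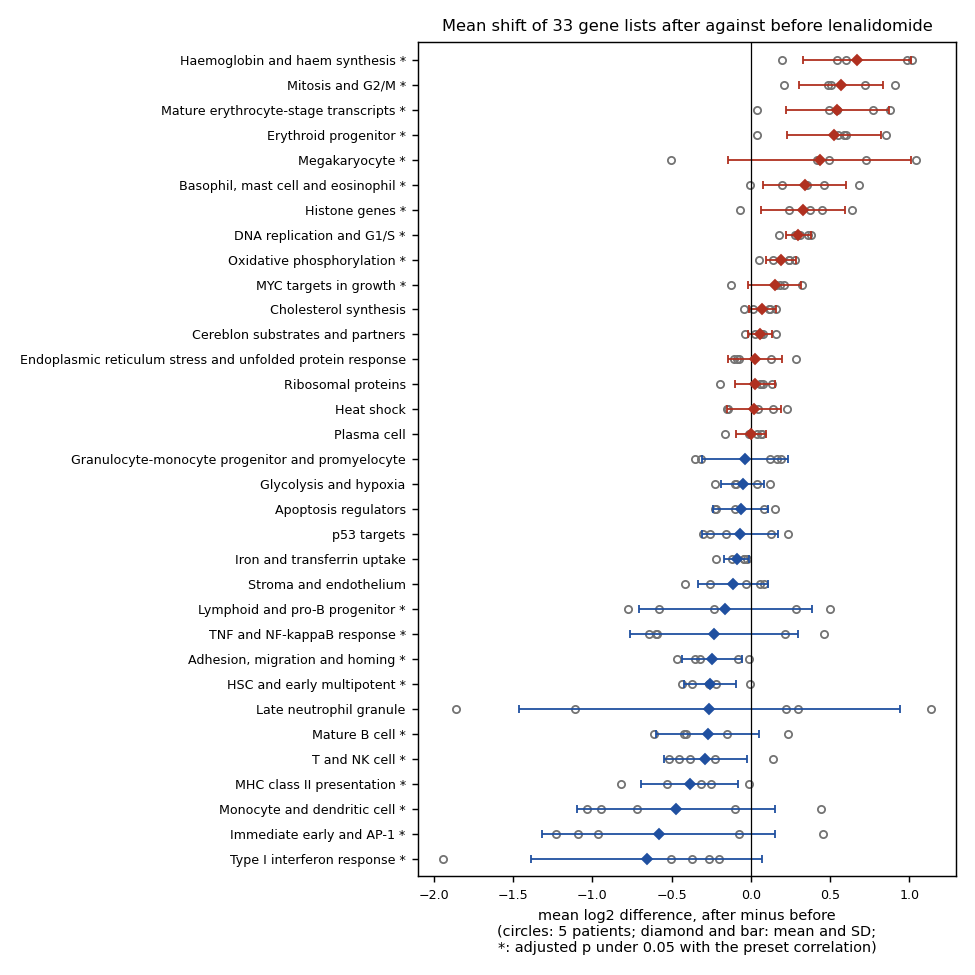
Mean log2 difference, after minus before lenalidomide, over the genes of each of 33 lists, with lists on the vertical axis. Circles are the 5 patients, the diamond and bar give mean and SD, and a star marks an adjusted p under 0.05 with the preset correlation; the haemoglobin list lies highest at 0.67 and the interferon list lowest at -0.66.

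Genes of red cell development lay higher after therapy. The haemoglobin and haem synthesis list had a mean shift of 0.67 ± 0.34 (SD, n = 5 pairs), and 12 of its 17 genes rose when adjusted over the list alone, with 0 over all genes tested. Among them were the delta-globin gene HBD at 1.35, the carbonic anhydrase gene CA2 at 1.23, HBB at 1.48 and UROD, an enzyme of haem synthesis, at 0.63. The erythroid progenitor list shifted by 0.53 ± 0.30, and 13 of 27 genes rose when adjusted over the list alone, XK, RHAG, the ankyrin gene ANK1 at 1.33 and the erythroid transcription factor gene GATA1 at 0.69 among them. The list of transcripts of mature erythrocytes shifted by 0.55 ± 0.32, with 4 of 16 genes higher when adjusted over the list alone, namely HBB, the globin chaperone gene AHSP at 1.83, CA1 at 0.82 and TRIM58 at 0.62. All 3 lists were higher in 5 of 5 patients, and 0 of their genes passed over all genes tested. Camera gave adjusted p values of 8.6e-10, 2.2e-10 and 2.0e-05 for the haemoglobin, erythroid and erythrocyte lists. With an estimated correlation the adjusted p was 0.314 for each.

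Megakaryocyte genes lay higher too, with more spread between patients. The list had a mean shift of 0.43 ± 0.58 (SD, n = 5 pairs), higher in 4 of 5 patients, and 5 of 22 genes rose when adjusted over the list alone, with 0 over all genes tested. They were LTBP1 at 1.51, GATA1 at 0.69, the von Willebrand factor receptor subunit GP1BA at 1.83, MMRN1 at 0.64 and the platelet integrin ITGA2B at 0.57. The adjusted p from camera was 2.8e-04, and the adjusted p was 0.465 with an estimated correlation. Leaving out 1 of the pairs gave a mean shift of 0.28, and leaving out another gave 0.67.

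Cell cycle genes lay higher after therapy as lists in 5 of 5 patients. The mitosis and G2/M list shifted by 0.57 ± 0.26 (SD, n = 5 pairs), a 1.48-fold difference, and 41 of 45 genes rose when adjusted over the list alone, with 0 over all genes tested. Examples were UBE2C at 0.85, the cyclin gene CCNB2 at 0.74, HMMR at 1.04 and BIRC5, which encodes survivin, at 0.64. The DNA replication and G1/S list shifted by 0.30 ± 0.080, and 19 of 42 genes rose when adjusted over the list alone, with 0 over all genes tested. Among them were the chromatin assembly gene CHAF1B at 0.45, the exonuclease gene EXO1 at 0.55, GINS3 at 0.53 and the polymerase subunit gene POLE2 at 0.52. By camera the adjusted p was 3.4e-28 for mitosis and 4.2e-14 for replication, and the adjusted p was 0.314 for both with an estimated correlation. The replication list was the 1 list that fry passed in its test of a shift to 1 side, with an adjusted p of 0.0278. In the same samples the erythroid list shifted by 0.53 and the haemoglobin list by 0.67, higher in 5 of 5 patients, and macrophage marker genes by -0.67, lower in 5 of 5. Without the 3 markers already seen the macrophage shift was -0.50.

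Histone, respiratory chain and growth genes lay higher as well. The histone list shifted by 0.33 ± 0.26 (SD, n = 5 pairs), higher in 4 of 5 patients, and 11 of 25 genes rose and 1 fell when adjusted over the list alone, with 0 over all genes tested. H2BC3, H3C3, H3C2 and H1-5 rose by 0.78, 0.79, 0.76 and 0.71, while H2BC21 fell by 0.77. The oxidative phosphorylation list shifted by 0.19 ± 0.095, higher in 5 of 5 patients, with 38 of 40 genes above 0 and 0 that passed over the list alone or over all genes tested. Its leading genes COX7B, NDUFA9, COX8A and ATP5F1B had differences of 0.38, 0.31, 0.42 and 0.32. The list of growth genes known as MYC targets shifted by 0.15 ± 0.17, higher in 4 of 5 patients, and 0 of 29 genes passed over the list alone or over all genes tested. NME1, WDR43, IMPDH2 and UTP20 had differences of 0.38, 0.38, 0.31 and 0.25, and MYC itself -0.03 ± 0.13 (SE), with -0.14 to 0.07 when a pair was left out. Camera's adjusted p was 8.8e-07 for histones, 3.9e-08 for oxidative phosphorylation and 5.2e-04 for MYC targets. With an estimated correlation the adjusted p was 0.392, 0.314 and 0.505. In the same samples the list of transcripts of mature erythrocytes shifted by 0.55. Macrophage marker genes shifted by -0.67, or by -0.50 without the 3 markers already seen.

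Stem cell genes lay lower after therapy, while early myeloid genes went both ways. The stem cell and early multipotent list shifted by -0.26 ± 0.17 (SD, n = 5 pairs), lower in 5 of 5 patients, 1 of them by only -0.006. When adjusted over the list alone 4 of 22 genes fell, with 0 over all genes tested. They were CRHBP at -1.36, PROM1, which encodes the stem cell surface protein CD133, at -0.74, RBPMS at -0.45 and HOPX at -1.44. CD34, the gene of the surface protein used for the selection, had a difference of -0.24 ± 0.17 (SE), lower in 3 of 5 patients, and did not pass. Without 1 of the pairs it had -0.37, and without each of 2 others -0.16 and -0.12. The adhesion, migration and homing list shifted by -0.25 ± 0.19, lower in 5 of 5 patients, 1 of them by only -0.014. Over the list alone 2 of 39 genes fell, with 0 over all genes tested. These were ICAM3 at -0.54 and the N-cadherin gene CDH2 at -0.67, while the leukocyte integrin genes ITGAL and ITGB2 had differences of -0.90 and -0.78. The adjusted p from camera was 1.5e-04 for the stem cell and 1.3e-04 for the adhesion list, and the adjusted p was 0.314 and 0.392 with an estimated correlation. Macrophage marker genes moved in the same direction as both lists, at -0.67 ± 0.46 (SD), or -0.50 without the 3 markers already seen. VCAM1 stood in both the marker list and the adhesion list.

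Progenitors of the lymphoid and the granulocyte-monocyte lineages showed no uniform shift. The lymphoid and pro-B list shifted by -0.16 ± 0.55 (SD, n = 5 pairs), lower in 3 of 5 patients, and 0 of 27 genes passed in limma's fit over the list alone, over all genes tested or at an unadjusted p under 0.05. IGLL1, ERG, POU2AF1 and SOX4 had differences of -0.39, -0.26, -0.47 and -0.17. Without 1 of the pairs IGLL1 had -0.23 and ERG -0.12, and POU2AF1 lay between -0.79 and -0.29. By camera the adjusted p was 0.0251, and the adjusted p was 0.697 with an estimated correlation. The call ended without each of 3 of the pairs in turn, at mean shifts of -0.14, -0.01 and -0.06, and the shift was -0.27 and -0.33 without the others. It also ended with a random patient effect, repeated quantile normalization, array quality weights, the order of handling as a term, the most variable probe set per gene and probe sets without the s or x mark, at shifts between -0.11 and -0.17. The granulocyte-monocyte progenitor list shifted by -0.04 ± 0.27 and was not called, with a log2 difference of -0.04 ± 0.20 (SE) for CEBPA and -0.36 ± 0.12 for SPI1, transcription factors of myeloid cells that did not pass. Of the genes of this list 13 lay above 0 and 15 below, with PRTN3 and ELANE at 0.99 and 0.70 against FCN1 and CSF1R at -2.38 and -0.98. With a pair left out the list ran from -0.09 to 0.04, and CEBPA lay between -0.20 and 0.11.

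Interferon-induced genes lay lower as a list in 5 of 5 patients, by very different amounts. The type I interferon list shifted by -0.66 ± 0.73 (SD, n = 5 pairs), with 34 of 35 genes below 0, and 3 fell when adjusted over the list alone, with 0 over all genes tested. They were the RNA sensor gene RIGI at -0.86, the interferon signalling factor IRF9 at -0.77 and OAS2 at -1.01, and IFI27 had a difference of -0.80. Camera's adjusted p was 1.3e-13, and the adjusted p was 0.392 with an estimated correlation. Without the pair that lay farthest from the others the shift was -0.34. Macrophage marker genes lay lower by -0.67 ± 0.46 (SD) in 5 of 5 patients in the same samples, and the monocyte and dendritic cell list by -0.47 ± 0.63 in 4 of 5. Without the 3 markers already seen the macrophage shift was -0.50, and CD163 stood in both of these lists.

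Immediate early and inflammatory response genes lay lower in most patients. The immediate early and AP-1 list shifted by -0.58 ± 0.73 (SD, n = 5 pairs), lower in 4 of 5 patients, and 0 of 28 genes passed over the list alone or over all genes tested, with 12 lower at an unadjusted p under 0.05 in limma's fit. FOSL2, DUSP1, DUSP2 and EGR1 had differences of -0.58, -0.57, -0.51 and -1.42, and DUSP2 had -0.33 without 1 of the pairs. These genes are known to answer to sample handling as well as to signals. The TNF and NF-kappaB list shifted by -0.23 ± 0.53, lower in 3 of 5 patients, and 4 of 30 genes fell over the list alone, with 0 over all genes tested, namely TNFAIP2 at -0.87, IRF1 at -0.57, and the chemokine genes CCL4 at -0.43 and CCL2 at -1.09. The adjusted p from camera was 3.9e-08 and 0.00189, and with an estimated correlation the adjusted p was 0.465 and 0.514. The call of the NF-kappaB list ended without 1 of the pairs, at -0.13, and its shift was -0.14, -0.14 and -0.41 without each of 3 others. Macrophage marker genes lay lower by -0.67 ± 0.46 (SD) in the same samples, or by -0.50 without the 3 markers already seen.

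Genes of MHC class II antigen presentation lay lower after therapy. The list shifted by -0.39 ± 0.31 (SD, n = 5 pairs), lower in 5 of 5 patients, 1 of them by only -0.010. Of its 17 genes 14 lay below 0. In limma's fit 0 genes passed over the list alone or over all genes tested, and 8 were lower at an unadjusted p under 0.05. CD74, the invariant chain, had a difference of -0.29, the protease gene CTSS -1.18, the transcriptional activator CIITA -0.44 and LGMN -0.21. Without 1 of the pairs CIITA had a difference of -0.29, and LGMN had 0.07, -0.36 and -0.35 without each of 3 pairs. Macrophage marker genes, with a mean shift of -0.67 ± 0.46 (SD), and the monocyte and dendritic cell list, with -0.47 ± 0.63, moved in the same direction. Without the 3 markers already seen the macrophage shift was -0.50, and CD163 stood in both of these lists. By camera the adjusted p of the MHC class II list was 2.0e-05, and the adjusted p was 0.314 with an estimated correlation.

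Markers of mature lymphocytes, cells that a CD34 selection is meant to remove, lay lower on balance. The T and NK cell list shifted by -0.29 ± 0.26 (SD, n = 5 pairs), lower in 4 of 5 patients, and 7 of 30 genes fell and 1 rose when adjusted over the list alone, with 0 over all genes tested. Genes of cytotoxic granules led the fall, with perforin, encoded by PRF1, at -1.25, granulysin, encoded by GNLY, at -1.06 and granzyme A, encoded by GZMA, at -0.92, next to the NK receptor gene KLRD1 at -0.70. GZMB, the gene that rose, encodes a cytotoxic protease that plasmacytoid dendritic cells are also known to make, and it stood in the monocyte and dendritic cell list too. The mature B cell list shifted by -0.27 ± 0.33, lower in 4 of 5 patients, and 1 of 15 genes fell over the list alone, the chemokine receptor gene CXCR5 at -0.42, with 0 over all genes tested. FCRL2, TNFRSF13B and CD37 had differences of -0.86, -0.33 and -0.36, and FCRL2 had -0.54 without 1 of the pairs. Camera's adjusted p was 2.0e-05 for T and NK cells and 5.6e-04 for B cells, and the adjusted p was 0.392 and 0.314 with an estimated correlation. Macrophage marker genes moved in the same direction in these samples, at -0.67 ± 0.46 (SD), or -0.50 without the 3 markers already seen.

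Some monocyte genes lay lower and some eosinophil genes higher, each within a mixed list. The monocyte and dendritic cell list shifted by -0.47 ± 0.63 (SD, n = 5 pairs), lower in 4 of 5 patients. When adjusted over the list alone 3 of its 24 genes fell, TYROBP at -1.34, CD163 at -1.34 and FCN1 at -2.38, and 2 rose, GZMB at 1.93 and the IgE receptor gene FCER1A at 0.86, with 0 over all genes tested. MS4A6A had a difference of -1.37, and of -0.84 without 1 of the pairs. Its call ended without each of 3 of the pairs in turn, at -0.41, -0.33 and -0.35, and with probe sets without the s or x mark, at -0.36. The basophil, mast cell and eosinophil list shifted by 0.34 ± 0.26, higher in 4 of 5 patients, and 4 of 22 genes rose over the list alone, with 0 over all genes tested. These were FCER1A, EPX at 1.87, the eosinophil lysophospholipase gene CLC at 1.00 and the interleukin-5 receptor gene IL5RA at 0.57, while HPGDS fell by 0.44. Its call ended without 1 of the pairs, at 0.31, in the fit without the pairing and in rank-based camera, where the shift was 0.34, with the order of handling as a term, at 0.30, and with probe sets without the s or x mark, at 0.43. The adjusted p from camera was 0.0281 for both lists, and the adjusted p was 0.505 for both with an estimated correlation.

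Plasma cell genes, which would mark myeloma cells among the selected cells, lay close to 0 as a list. The plasma cell list had a mean shift of 0.0008 ± 0.096 (SD, n = 5 pairs), and 0 of 25 genes passed in limma's fit over the list alone, with 2 higher and 1 lower at an unadjusted p under 0.05. IRF4, a transcription factor of plasma cells and of dendritic cells, had a difference of 1.01 ± 0.25 (SE), higher in 5 of 5 patients, with an adjusted p of 0.167 over all genes. The late neutrophil granule list shifted by -0.26 ± 1.20 and the stroma and endothelium list by -0.11 ± 0.22. The late neutrophil list was called lower without each of 3 of the pairs in turn, at -0.40, -0.61 and -0.38, and shifted by 0.14 without another. With the order of handling as a term it was called too, at -0.36. The stroma list was called lower without 1 of the pairs, at -0.16.

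Genes of the drug's target complex went both ways by small amounts. The list of cereblon substrates and partners shifted by 0.06 ± 0.074 (SD, n = 5 pairs), and 0 of 19 genes passed in limma's fit over the list alone, with 2 higher and 1 lower at an unadjusted p under 0.05. These 3, chosen after their values were seen, were the ligase subunit gene RBX1 at 0.39 ± 0.10 (SE) and GSPT1 at 0.25 ± 0.10, both higher in 5 of 5 patients, and the glutamine synthetase gene GLUL at -0.41 ± 0.12, lower in 5 of 5. Fry's test of change in either direction gave the list an adjusted p of 7.5e-04, and its test of a shift to 1 side 0.0996. CRBN had a difference of -0.07 ± 0.10 (SE), IKZF1 0.11 ± 0.12, IKZF3 -0.25 ± 0.33 and the casein kinase gene CSNK1A1 0.15 ± 0.094, with adjusted p over all genes of 0.758, 0.706, 0.760 and 0.480. With a pair left out, the list ran from 0.03 to 0.08 and CRBN lay between -0.14 and -0.02. IKZF1 ran from -0.01 to 0.15 and IKZF3 from -0.62 to 0.05. Of 4 probe sets for IKZF1, 3 had the direction of the mean. The array measures RNA, while the drug is known to act on the proteins encoded by IKZF1 and IKZF3.

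Genes of iron handling went both ways, and the mean shifts of stress lists lay near 0. Camera did not call these lists, while fry's test of change in either direction gave an adjusted p of 7.5e-04 for iron and 0.00188 for apoptosis. The iron and transferrin uptake list shifted by -0.09 ± 0.080 (SD, n = 5 pairs), lower in 5 of 5 patients, and its genes went both ways. Over the list alone HMOX1 and the ferritin light chain gene FTL fell, by 1.71 and 0.58, while ACO1 rose by 0.62 and STEAP3 by 0.46. The lists of heat shock, of endoplasmic reticulum stress and of ribosomal proteins shifted by 0.02 ± 0.17, 0.03 ± 0.17 and 0.03 ± 0.13. Of the heat shock genes 14 of 16 lay above 0, with a median gene at 0.13, while HSPA6 stood at -1.81. Cholesterol synthesis, glycolysis and hypoxia, and p53 targets shifted by 0.07 ± 0.085, -0.05 ± 0.13 and -0.07 ± 0.24. With a pair left out, the glycolysis list ran from -0.10 to -0.01 and p53 targets from -0.15 to -0.01. The apoptosis list had a mean shift of -0.06 ± 0.17 and a median gene at 0.02, of opposite sign, and over the list alone BIRC5 rose by 0.64 and CASP10 fell by 0.37. DDIT4, a gene induced by stress and hypoxia, fell by 0.76 over the glycolysis and endoplasmic reticulum stress lists alone. Heat shock genes were called higher without each of 2 of the pairs, at 0.06 each, and at 0.02 with centred samples and in rank-based camera, and ribosomal protein genes without 1 of them, at 0.08.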

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

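The tests on mature cells, on T cells and on macrophages were chosen after the shifts of the fixed lists and some of the genes tested had been seen.

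Of 138 lists and genes examined, 8 had 1 of the 5 paired differences far from the other 4, where chance gives about 6.9. The ratio of that gap to the whole range was 0.824 for the type I interferon list, whose far pair shifted by -1.94 against -0.51 to -0.20 in the others. It was 0.717 for IFIT1, with -3.82 against -1.31 to -0.32, and 0.813 for OAS2, with -2.10 against -0.91 to -0.64. The ribosomal protein list had a ratio of 0.770, with -0.19 against 0.06 to 0.13. DUSP2 had 0.837, with -1.25 against -0.42 to -0.26, and PROM1 0.883, with -1.32 against -0.65 to -0.56. TRIM58 had 0.731, with 1.24 against 0.33 to 0.57, and IKZF1 0.806, with 0.56 against -0.06 to 0.06.

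Other splits of the 10 samples gave results as large as the real one. With 100 of the 126 splits into 2 groups of 5, 9 gave at least the 1 gene that passed the adjustment, 20 gave at least the 421 genes at an unadjusted p under 0.05 with a fold of at least 1.5, and 20 gave at least the 20 called lists, so chance cannot be excluded for any of the 3. The highest counts of the other splits were 190 genes, 992 genes and 23 lists. The gene counts of 190 and 992 lay well above the real 1 and 421, and 23 lists lay close to the real 20. With the patient as a block, a split that parts only some pairs draws on fewer patients. Some of these splits still compare before with after, so they cannot tell that difference from another structure of the samples. The source of the high counts was not tested. Among the 16 splits that part all 5 pairs as the real one does, the highest other counts were 0 genes, 384 genes and 21 lists, and 16 splits are too few for a share under 0.05.

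Cycling and erythroid genes lay higher after therapy, with mean shifts of 0.57 ± 0.26 and 0.53 ± 0.30 in 5 of 5 patients. RNA integrity as the cause would move the 3′ minus 5′ value of the ACTB and GAPDH controls 1 way, but 2 patients had a positive and 3 a negative shift, with a mean of -0.017 ± 0.32. Noise in these controls would also give mixed signs, and control and list shifts were not compared patient by patient. The controls therefore cannot exclude RNA integrity. The order of handling, taken from sample numbers that no label calls an order, would turn the sign of the shifts, but mitosis shifted by 0.635 and erythroid genes by 0.66 in the 3 patients with the after sample numbered first, and by 0.465 and 0.32 in the other 2. Fewer mature cells carried over would raise all progenitor lists alike, while the stem cell list lay below the erythroid list by a difference of -0.785 ± 0.33. Both shifts were known when this test was chosen, so its outcome was settled beforehand and it gives no independent support. It covers only a loss of mature cells, while the list of transcripts of mature erythrocytes rose by 0.55 ± 0.32 in 5 of 5 patients. Chance stays open, and no biological explanation was tested.

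T and NK cell genes lay lower, and the cells of the selection could hold fewer mature T cells after therapy. Core T cell genes had a median difference of -0.174, with 9 of 12 genes lower, against -0.704 for 10 genes of cytotoxic effector cells, 9 of them lower. The cytotoxic list leaves out GZMB, which differed by 1.93. A loss of T cells alone would lower the core genes at least as much as the cytotoxic genes. Yet the values hold no level, and a core T cell gene close to background cannot fall far. This explanation therefore cannot be told apart from others, such as a change within the cytotoxic cells. The cytotoxic genes do not separate T from NK cells, and a change in the number of NK cells was not tested. Of the core genes, TRBC1, CD8A, CD3G, CD3D, BCL11B and LTB had differences of -0.73, -0.57, -0.40, -0.37, -0.35 and -0.31, CD3E, LCK, IL7R, CD5 and CD6 of 0.04, 0.03, -0.01, -0.04 and -0.03, which go against a loss of T cells if these genes lie above background, and CD2 of 0.41. The CD34 selection should remove these cells, and 10 of the 12 core and all 10 cytotoxic genes also stood in the lists fixed beforehand.

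HMOX1 had a log2 difference of -1.71, lower in 5 of 5 patients. A general decline of the antioxidant response would lower other targets of it, of which 7 of 10 were measured. They had a median difference of 0.109, with 5 of 7 above 0, while FTL stood at -0.58, lower in 5 of 5 patients. These values go against a general decline only if the targets lie above background. The values hold no level, so this is unknown. Fewer marrow macrophages carried over may account for HMOX1, since 17 macrophage markers had a median difference of -0.511, with 14 lower and the mean lower in 5 of 5 patients. MSR1, CD5L and CD163 of this list, already seen among the named genes, had differences of -1.71, -1.35 and -1.34. Without them the other 14 markers had a median of -0.44, with 11 lower. Among these, C1QB and CTSD stood at -1.11 and -0.40, VSIG4 at -0.07, and LYVE1, MRC1 and AXL at 0.04, 0.25 and 0.28. The CD34 selection should remove macrophages, 2 of the 17 genes also stood in the lists fixed beforehand, and a change of HMOX1 within the progenitors was not tested.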

How the results depend on the processing

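The alternatives on the spread of genes, the most variable probe set, probe sets without the s or x mark and the robust variance were chosen after seeing the data. The filters on dim probes, the probe set with the highest mean and the trend of variance on level were not run, since the values hold no level, and signal over background stays unknown.

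The number of genes past the adjustment moved from 1 to 4 without the pairing (2 higher, 2 lower), to 29 with the patient as a random block, 2 after repeated quantile normalization, 172 with array quality weights, 41 with the order of handling as a term and 0 in a plain paired test. It was 24 without the 25% and 30 without the 50% of genes with the smallest SD, where fewer genes were tested, and 2 without s or x probe sets. Leaving out each pair gave 0 to 102 genes. HMOX1 passed in 12 of 17 alternatives, with log2 differences from -1.80 to -1.63 and adjusted p from 0.00428 to 0.233. The 421 genes at 1.5-fold became 231 in the plain paired test, 137 higher and 94 lower, and 346 to 582 with a pair left out, 179 to 220 of them higher and 166 to 365 lower. Array quality weights gave 211 higher and 345 lower. The 20 called lists became 0 with an estimated correlation and 1 with fry's test of a shift to 1 side, and 17 to 22 otherwise. The fit without the pairing ended 1 call of a list, basophil, mast cell and eosinophil, and no other list's. Of the 20 lists, 16 were called with any pair left out, and no called list turned its direction. The causes of these changes were not tested, also where fewer genes were tested. The SD of that filter was taken over all 10 samples, so it favours genes that differ between the groups.

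Lists that were not called and single genes near 0 turned in sign. The apoptosis list was 0.0157 by its median. Heat shock was -0.00739 with array weights, -0.0232 and -0.0744 without the 25% and 50% least variable genes, -0.228 without s or x probe sets, and -0.0300 to 0.0647 with a pair left out. Plasma cell was -0.00159 with centred samples, -0.00939 with the order term, -0.00308 without the 25% least variable genes, and -0.0171 to 0.0412 with a pair left out. Stroma was 0.0132 without s or x probe sets. With a pair left out, endoplasmic reticulum stress ran from -0.0353 to 0.0619, the granulocyte-monocyte list from -0.0942 to 0.0410 and late neutrophil from -0.613 to 0.136. Uncalled lists that kept their sign but moved over 1.5 times with a pair left out ran from -0.0953 to -0.00861 (glycolysis), -0.147 to -0.0129 (p53), -0.117 to -0.0225 (apoptosis), -0.161 to -0.0358 (stroma), -0.107 to -0.0583 (iron), 0.0310 to 0.0815 (cereblon) and 0.000973 to 0.0825 (ribosomal). IKZF1 was -0.318 with its most variable probe set and -0.106 without s or x probe sets, and MYC 0.00262 with array weights. With a pair left out, IKZF1 ran from -0.00594 to 0.147, IKZF3 from -0.619 to 0.0496, MYC from -0.135 to 0.0665, CEBPA from -0.202 to 0.115 and LGMN from -0.358 to 0.0732. The cause was not tested.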

Other observations

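The genes below were chosen after their values were seen, and none passed limma's adjustment over all genes. Genes of the basophil, mast cell and eosinophil list differed widely. PRG2 and PRG3, which encode the major basic proteins of eosinophil granules, had log2 differences of 1.03 ± 0.35 and 1.55 ± 0.60 (SE, n = 5 pairs), each higher in 4 of 5 patients, next to EPX at 1.87 ± 0.34, while SIGLEC8, also known from eosinophils, had -0.06 ± 0.11. Of genes known from mast cells and basophils, HPGDS stood at -0.44 ± 0.098, lower in 5 of 5 patients, TPSB2 at -0.14 ± 0.11, and TPSAB1, CPA3 and HDC at -0.01 ± 0.12, 0.03 ± 0.20 and 0.09 ± 0.13. IL1RL1 stood at 0.31 ± 0.11, SLC18A2 at 0.37 ± 0.19 and FCER1A at 0.86 ± 0.14, higher in 5 of 5. Platelet genes differed in direction, with PF4 at 1.26 ± 0.50 and SELP at 1.33 ± 0.42 against PPBP at -0.95 ± 0.72. The difference between these sets of genes was not tested.

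Some genes known from plasmacytoid dendritic cells lay higher next to GZMB at 1.93 and IRF4 at 1.01. No list of these cells alone was tested, and the monocyte and dendritic cell list, which holds GZMB, shifted by -0.47 ± 0.63 (SD). SERPINF1 had a difference of 0.95 ± 0.14 (adjusted p = 0.0888), higher in 5 of 5 patients, and CUX2 and LILRA4 had 1.44 ± 0.42 and 0.55 ± 0.22, higher in 4 of 5. Other genes of these cells did not follow, with IL3RA at 0.04 ± 0.12, TCF4 at 0.11 ± 0.12 and IRF7 at -0.20 ± 0.11. The adhesion gene EPCAM, known from early erythroid progenitors among other cells, differed by 1.43 ± 0.18, the transcription factor gene WT1 by 0.80 ± 0.09 and the erythroid transcription factor gene KLF1 by 0.90 ± 0.16, each higher in 5 of 5 patients. Of the GIMAP genes, GIMAP4 stood at -2.30, GIMAP6 at -0.52 ± 0.26 and GIMAP5 at -0.02 ± 0.11.

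Of the 3151 probe sets with no named gene or with several, 0 passed limma's adjustment, and 329 had an unadjusted p under 0.05 against 158 by chance.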
